A study of Papio anubis with 2 samples.

How the data were processed

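Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to cells from the subventricular zone (SVZ) of an adult olive baboon (Papio anubis) brain. The SVZ is a layer along the lateral ventricles that holds neural progenitors in adult mammals. Per the labels' protocols, dissociated SVZ cells were captured on magnetic beads carrying antibodies to markers of glial and progenitor cells (GFAP, Vimentin and Nestin among them) or of young neurons (Doublecortin, PSA-NCAM). The captured cells were fixed in 1.1% formaldehyde, and chromatin was sheared to 200 to 500 bp. One aliquot was precipitated with antibodies to H3K4me3, the trimethylated form of histone H3 lysine 4, a mark of the start sites of active or poised genes. Another aliquot was precipitated with an antibody to total histone H3, which per the labels' protocols served for normalisation. Each antibody has 1 library, and the labels do not say which of the marker antibodies was used for the cells in these libraries.

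The deposited data analysed here are 1 peak list, that of the H3K4me3 library; no values of the total H3 library were analysed here. The authors' list gives the positions of peaks on the rhesus macaque assembly rheMac2, per the file name, which also gives a false discovery rate of 0.01. The submitters' processing notes name Bowtie version 0.12.7, a short-read aligner. The peak caller, its settings and whether total H3 served as background in calling are not given in the sources used here. The list has 3 columns (sequence, start and end) and no height, score, enrichment or p-value, so peaks could not be ranked by strength. Baboon reads placed on a macaque assembly can be lost where the species differ, and can pile up where the assembly holds fewer copies of a sequence than the baboon genome. The number of reads is unknown, so no precision that depends on read depth could be given. Exact and Wilson intervals (both at 95%) cover counting error over peaks only. Peaks that lie together are not independent, so intervals for shares of peaks are too narrow.

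Start positions were read as counted from 0, as in BED files, and are printed counted from 1. The only gene table at hand was of another assembly, a baboon one, and positions were not converted between assemblies. Peaks were therefore not tied to genes. The planned shares of peaks and genes at start sites and the tests of 16 gene lists fixed beforehand (progenitor, neuroblast, neuronal, glial, vascular, immune, cell cycle, translation, metabolic, chromatin and signalling genes, HOX genes and controls) were not run. The planned correlation of width with score and the stricter threshold by score were not run either, since the list has no score. The substitute threshold by width could not be formed because 98.6% of the peaks tie at 1 width.

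Neighbouring peaks were linked into groups where the gap between them was at most 10 kb. The share of neighbouring pairs within that gap and the share of peaks in groups of 3 or more were compared with 1000 random placements of peaks of the same widths, without overlap, on the same sequence; the one-sided permutation p counts placements at least as high. The smallest p these placements can give is 0.001. Random placement ignores where genes and mappable sequence lie. In an alternative, each peak was instead moved by up to 5 Mb from its own position. This keeps density over stretches longer than the shift, but not at 1 Mb or below. Chromosome length was taken as the end of the last peak, since no rheMac2 genome was used. Counts per chromosome were set against those expected from length, with exact Poisson intervals and exact two-sided binomial tests adjusted by Benjamini-Hochberg over 21 chromosomes, for peaks and for linked groups counted once. Correlations with length used 100000 permutations. Peaks, groups and chromosomes are not biological replicates, and every p-value describes this 1 list, not variation between animals.

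Most regions named in the text follow a rule set before the data were examined: the 10 widest peaks, the 3 linked groups with the most peaks, the 5 windows of 1 Mb with the most peaks, and the chromosomes with the 2 highest and 2 lowest ratios of observed to expected peaks. Chromosomes 1, 9, 13, 16 and 18 and the widest joined interval, on chromosome 8, fall outside that rule and were chosen after their values were seen. Alternatives covered the linking gap (2, 5, 20 and 50 kb), merging of peaks (gaps of up to 500 bp, 1 kb and 2 kb), the length measure, the autosomes alone, the unplaced sequence, and width limits; those added after the data were seen were counting each linked group once, leaving out groups of 10 or more peaks, leaving out the unplaced sequence from both shares of grouping, the 5 Mb placement for the share in groups of 3 or more, the class of peaks wider than the commonest width, and the other linking gaps, the merging and the leaving out of chrUr for the number of groups of 10 or more. The comparison of spacing between group sizes was also chosen after the data were seen. The scripts were tested on simulated data. Of 100 simulated sets of 9808 ungrouped peaks, 4% reached a p under 0.05, and 40 of 40 planted groups were recovered. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.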

Results

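The study profiled H3K4me3, a histone mark of the start sites of active or poised genes, in cells purified from the subventricular zone of an adult baboon brain, which the labels call neural progenitors, with total histone H3 from the same kind of chromatin as the normalising library. There was 1 library per antibody and no second animal, so no difference between antibodies or animals could be tested. The H3K4me3 list held 9910 peaks on rheMac2, of which 9604 lay on chromosomes 1 to 20, 204 on chromosome X and 102 on the unplaced sequence chrUr. No 2 intervals were identical. The intervals add up to 1.502 Mb, which follows from their number and near-constant width and is not a measure of how much sequence carries the mark. The mean density over the 21 chromosomes was 3.43 peaks per Mb. Read depth was unknown. Peaks were not tied to genes, so regions are given by position on rheMac2 without a statement on the gene, exon or intron there.

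The first question was how wide the listed intervals were. They were short and nearly uniform. Of the 9910 peaks, 9770 were 150 bp wide, which is 98.6% (95% Wilson interval 98.3% to 98.8%), and the other 140 were 190 to 390 bp wide. Starts fell on a grid of 20 bp. A width and grid this regular can be set by the peak caller, which is not named in the sources used here, so 150 bp is not a measure of the extent of the mark at a site. The widest peak, of 390 bp, lay on chromosome 10 at 13506002 to 13506391. Peaks of 370 bp lay on chromosome 6 at 31602862 to 31603231 and on chromosome 16 at 69666522 to 69666891. Peaks of 350 bp lay on chromosome 1 at 138883562 to 138883911 and on chromosome 6 at 156395282 to 156395631. The next 4, of 310 bp, lay on chromosome 14 at 88064242, 88119702 and 88173462 and on chromosome 19 at 45274682, and the tenth place was shared by 26 peaks of 290 bp. The 95th percentile of width was 150 bp, equal to the smallest width, so the planned class of broad domains contained every peak and separated nothing. No single interval reached 2 kb.

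Wider regions could be read only from runs of neighbouring peaks. When peaks with gaps of up to 1 kb were joined, 6010 intervals resulted, with a median width of 150 bp. Of these, 281 (4.68%) were at least 2 kb wide, 103 at least 4 kb and 15 at least 10 kb. The widest joined interval, of 21.8 kb, lay on chromosome 8 at 3462 to 25231, inside a linked group of 64 peaks from 202 to 62631. The 10 widest joined intervals all lay inside linked groups of 10 or more peaks, whose origin is left open below. A joined interval is a run of peaks and need not be 1 broad marked region.

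The second question was whether H3K4me3 peaks lay in groups. Many had a close neighbour. Of 9888 neighbouring pairs on the same sequence, 5287 (53.5%, Wilson interval 52.5% to 54.5%) were within 10 kb, against a median of 4.70% (95% range 4.33% to 5.08%) in random placements of the same peaks. Gaps of at most 500 bp made up 29.1% of the pairs and gaps above 100 kb made up 34.4%. Groups of 3 or more linked peaks held 5001 peaks, 50.5% of the list (Wilson interval 49.5% to 51.4%), against 1.45% (1.24% to 1.71%) in random placements. The 102 peaks of chrUr, with its length taken as the end of its last peak, carry much of that random value. Without chrUr the share was 49.98% against 0.459% (0.245% to 0.704%) at random. Both shares exceeded all 1000 placements (one-sided permutation p = 0.001, the smallest they can give). Without the groups of 10 or more peaks the shares fell to 27.9% against 2.504% at random and to 20.99% against 0.322% at random, with the same permutation p of 0.001. Of all 9888 neighbouring pairs, 3900 were within 1 kb, and 1 marked region can be listed as several short intervals. Placing each interval alone ignores this, so these p-values can partly reflect how regions are cut up. With peaks merged at 1 kb the shares were 23.2% against 2.79% at random and 21.5% against 0.765% at random, with the same permutation p.

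**Figure D1:**
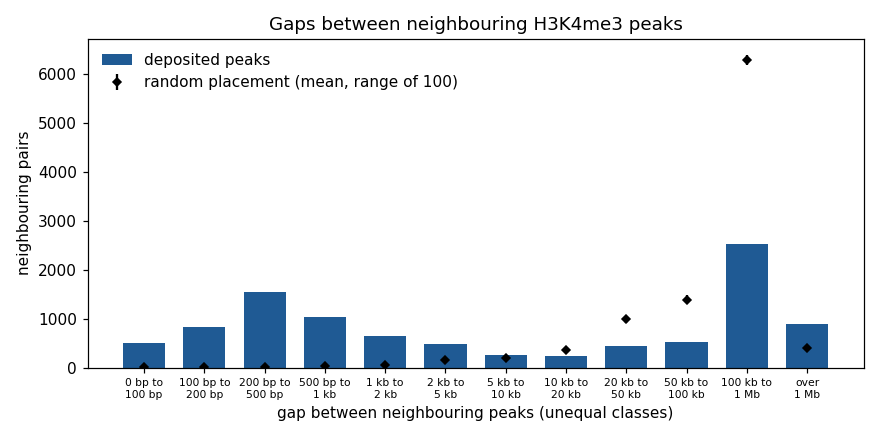
Gaps between neighbouring H3K4me3 peaks, in unequal classes on the horizontal axis, with the number of neighbouring pairs on the vertical axis. Bars are the deposited peaks, and diamonds with lines are the mean and range of 100 random placements. Gaps of 200 to 500 bp numbered 1541 against a random mean of 19.4, and gaps of 100 kb to 1 Mb numbered 2522 against a random mean of 6299.

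Linking at 10 kb gave 4623 groups of 4 kinds. Isolated peaks made up 3441 groups, 34.7% of all peaks (Wilson interval 33.8% to 35.7%). Another 734 groups were pairs, with a median span of 0.61 kb (quartiles 0.41 and 1.27 kb). Groups of 3 to 9 peaks numbered 310 and held 13.2% of the peaks, with a median span of 3.24 kb (quartiles 1.43 and 7.55 kb). The 138 groups of 10 or more peaks were 2.99% of the groups but held 3697 peaks, 37.3% of the list (Wilson interval 36.4% to 38.3%). Their median span was 20.7 kb (quartiles 13.3 and 34.8 kb), with a median density of 0.964 peaks per kb (quartiles 0.761 and 1.37). They occurred on every sequence of the list except chromosome 2, with 5 of them on chrUr. Their number depends on how peaks are counted: with peaks first merged at 1 kb, there were 29 groups of 10 or more intervals, against at most 3 at random.

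The 3 groups with the most peaks lay inside chromosomes 13, 6 and 11. On chromosome 13, 145 peaks spanned 163.5 kb from 87522942 to 87686391. On chromosome 6, 126 peaks spanned 163.4 kb from 46400002 to 46563351. On chromosome 11, 91 peaks spanned 81.9 kb from 35934602 to 36016511. The density in these groups was 0.887, 0.771 and 1.11 peaks per kb.

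**Figure D2:**
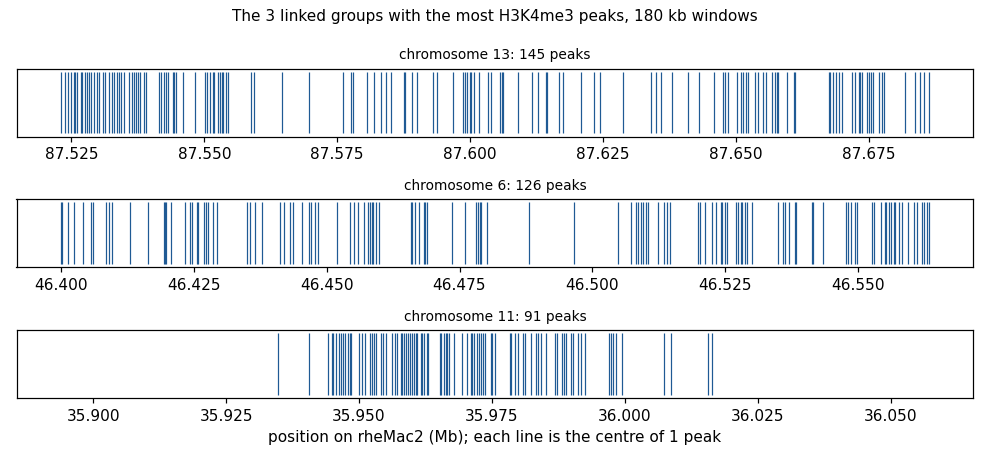
The 3 linked groups with the most H3K4me3 peaks, each drawn in a window of 180 kb, with the position on rheMac2 in Mb on the horizontal axis and 1 line at the centre of each peak. The groups on chromosomes 13, 6 and 11 hold 145, 126 and 91 peaks, and peaks are spread along each whole span.

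Spacing within the groups differed by group size. Among pairs with a gap of at most 1 kb, the median distance between peak centres was 320 bp (quartiles 240 and 640 bp, n = 558), and the fullest class of 100 bp was 200 to 300 bp. In groups of 10 or more, the median over all such neighbours was 480 bp (quartiles 340 and 680 bp, n = 2696), and the fullest class was 300 to 400 bp. For the test, 1 distance was drawn at random from each of the 138 large groups and set against the 558 pairs. Over 20 such draws the median in large groups was 120 to 210 bp longer, and the two-sided permutation p was at most 0.00031. Neighbours within 1 kb in random placements had a median centre distance of 654.5 bp (95% range 488 to 799.6 bp).

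At the scale of 1 Mb, 2027 of 2871 windows (70.6%) held a peak and the median window held 1. The 30 windows with 50 or more peaks held 28.9% of the peaks on chromosomes. The fullest were 35 to 36 Mb of chromosome 11 with 270 peaks, 0 to 1 Mb of chromosome 9 with 257, 66 to 67 Mb of chromosome 14 with 177, 87 to 88 Mb of chromosome 13 with 154 and 32 to 33 Mb of chromosome 3 with 143. These 5 windows held 1001 peaks, 10.2% of those on chromosomes. Counted as linked groups, the same windows held 14, 10, 15, 8 and 9 groups.

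The third question was how the mark was shared among chromosomes. Peak density was highest on chromosome 19, at 6.57 peaks per Mb, followed by chromosome 14 at 5.20. It was lowest on chromosome X, at 1.34 peaks per Mb, followed by chromosome 20 at 1.78. As background, macaque chromosomes 19 and 20 correspond to human chromosomes 19 and 16, which are both gene-rich. Relative to its length, chromosome 19 carried 1.92 times the expected peaks (exact 95% Poisson interval 1.74 to 2.11) and chromosome 14 carried 1.52 times (1.41 to 1.63). Chromosome X carried 0.389 times (0.338 to 0.447) and chromosome 20 carried 0.519 times (0.441 to 0.607). The sex of the animal and the copy number of X were not examined, so the ratio of X does not measure the mark per copy. In exact binomial tests, 9 chromosomes were higher and 10 lower than expected at an adjusted p under 0.05. Peaks in a group are not independent, so these intervals are too narrow.

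With each linked group counted once, 6 chromosomes (1, 7, 11, 14, 16 and 19) were higher and 4 (5, 13, 18 and X) were lower in the same exact test. Linked groups are not independent of each other either, so the intervals here are too narrow and the p-values too small. Calls near the threshold, such as that of chromosome 13, are the least secure. Chromosome 19 held 2.07 times the expected groups (1.80 to 2.37, exact adjusted p = 3.9e-21), and chromosome 16 held 1.43 times (1.23 to 1.65, exact adjusted p = 2.8e-05). Chromosome X held 0.418 times (0.341 to 0.507, exact adjusted p = 1.9e-24), and chromosome 18 held 0.599 times (0.467 to 0.755, exact adjusted p = 1.7e-05). Chromosome 20 was not called by groups, at 0.851 times (0.706 to 1.02, exact adjusted p = 0.12). That does not show that its deficit is gone. With groups of 10 or more peaks left out, its ratio by peaks was 0.713 (0.598 to 0.843). Chromosomes 13 and 1 changed direction, with both counts past the threshold. Chromosome 13 went from 1.44 times by peaks to 0.840 times by groups (0.724 to 0.970; exact adjusted p = 0.028), and 63.1% of its peaks were in groups of 10 or more. Chromosome 1 went from 0.902 times by peaks (0.837 to 0.971; exact adjusted p = 0.0043) to 1.17 times by groups (1.06 to 1.29; exact adjusted p = 0.0025), and 15.6% of its peaks were in such groups.

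**Figure D3:**
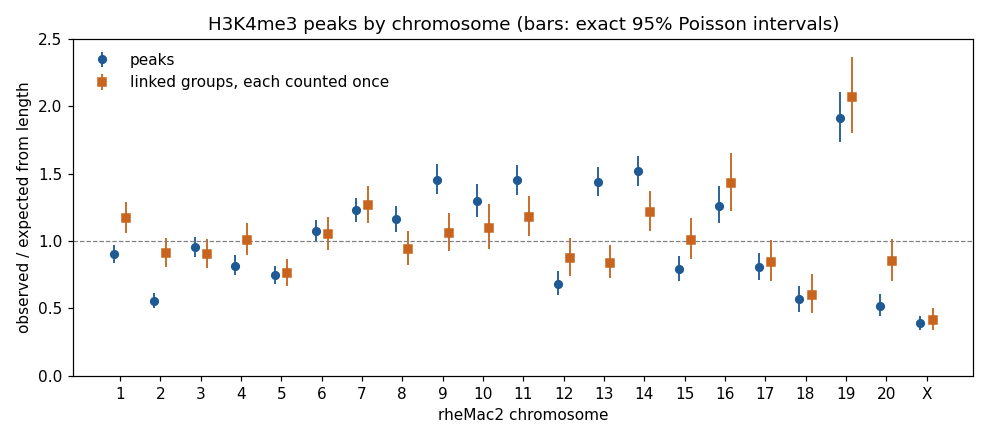
Observed over expected counts per rheMac2 chromosome, with circles for peaks and squares for linked groups counted once. Bars are exact 95% Poisson intervals, and the dashed line marks the number expected from length. Chromosome 19 stands highest at 1.92 and 2.07 and chromosome X lowest at 0.389 and 0.418, while chromosome 13 moves from 1.44 to 0.840 and chromosome 1 from 0.902 to 1.17.

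Peak number rose with chromosome length across the 21 chromosomes, with Pearson r = 0.59 (two-sided permutation p = 0.0059) and Spearman rho = 0.55 (permutation p = 0.012). Without chromosomes 1 and 19, the farthest from the median length, r was 0.57 (permutation p = 0.013). Linked groups counted once gave r = 0.77 (permutation p = 9.0e-05) and rho = 0.75 (permutation p = 0.00016). The relation is across chromosomes of 1 library.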

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

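The 102 peaks on the unplaced sequence chrUr entered no comparison between chromosomes. They were noted because a signal in such sequence stands outside the main measurement; they are 1.03% of the list and all lie between positions 10402 and 391171. They formed 12 linked groups, of which 5 held 10 or more peaks. Random placement of the whole list gave a median of 4 such groups (95% range 2 to 6), and 0 in each of 1000 placements without chrUr. In those placements the length of chrUr was taken as the end of its last peak, which packs its 102 peaks into 391171 bp. That packing alone gives groups of 10 or more, so the comparison cannot say whether 5 such groups on chrUr are unusual. The sequence has no known place on a chromosome, and no explanation was tested.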

How the results depend on the processing

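Both shares that describe grouping stayed above every random placement under all 8 alternatives tried for each, with the same permutation p of 0.001. The share of neighbouring pairs ranged from 23.2% (peaks merged at 1 kb) to 60.3% (gap of 50 kb), and the share in groups of 3 or more from 20.99% (without groups of 10 or more) to 58.1% (gap of 50 kb). When each peak was moved by up to 5 Mb, the random medians were 10.1% and 5.38%. The correlation of peak number with chromosome length kept its sign and its permutation p under 0.05 in all 5 alternatives (r from 0.59 to 0.77). The number of peaks depended on merging by construction, with 6010 after merging at 1 kb, 5367 at 2 kb, and 4623 linked groups at 10 kb. Broad domains depended wholly on their definition: 9910 at the 95th percentile, 0 at 2 kb or at 4 kb, 304 in peaks merged at 1 kb, and 140 wider than the commonest width. Groups of 10 or more peaks numbered 138, 113 to 147 at the other linking gaps, 133 without chrUr and 29 after merging at 1 kb. Ratios for chromosomes 19 and X stayed on their side of 1 in all alternatives. Chromosome 20 rose from 0.519 to 0.729 with peaks merged at 1 kb, 0.713 without groups of 10 or more, and 0.851 with groups counted once; chromosome 14 fell from 1.52 to 1.22 with groups counted once. Chosen after the data were seen were counting groups once, leaving out large groups, leaving out chrUr from both shares, the 5 Mb placement for the share in groups of 3 or more, the class wider than the commonest width, and the settings given here for groups of 10 or more. Alternatives that need a score or a rheMac2 annotation were not run, and with 1 library no replicate could be left out. Depth is unknown, so the absence of a peak does not show absence of the mark.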

Other observations

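The list also left long stretches without H3K4me3 peaks. Of 2871 windows of 1 Mb, 844 (29.4%) held no peak, against a median of 180 (95% range 161 to 200) when peaks were placed at random and 625 (594 to 657) when linked groups were placed at random (one-sided permutation p = 0.001 for both, the smallest 1000 placements can give). The longest peak-free stretch, of 13.6 Mb, lay on chromosome 20 from 31037152 to 44638081. The next were 9.49 Mb on chromosome X from 76970972 to 86458361, 9.18 Mb on chromosome X from 105039072 to 114219381, and 8.76 Mb on chromosome 19 from 23884472 to 32648341. These stretches were chosen after their values were seen, and centromeres and assembly gaps within them were not examined. Peaks wider than 150 bp were in groups of 10 or more in 29.3% of cases (Wilson interval 22.4% to 37.3%), against 37.4% of peaks of 150 bp (36.5% to 38.4%; Fisher's exact two-sided p = 0.053). All peaks of a group share its size and are not independent, so these intervals and this p overstate the precision.

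The tests of random placement for the number of groups of 10 or more, of the first 1 Mb and of chromosomes 19, 14 and 9 were chosen after the results were seen. The predictions for regional density and tandem copies were written after the dense groups had been seen, but before the results of those 2 tests. The pattern a reader would most want to follow up is the 138 groups of 10 or more peaks, which spread over a median of 20.7 kb and hold 37.3% of the list; with peaks first merged at 1 kb there are 29. The values argue against 2 explanations, uniform placement and tandem copies, each in a limited form. The test of regional density could not decide. Uniform random placement gave at most 7 such groups, and 0 without chrUr, where 133 were observed. With peaks merged at 1 kb it gave at most 3, against 29. Moving each peak by up to 5 Mb, which keeps density only over stretches longer than the shift, gave at most 8, with chrUr included. Each interval was moved alone, so a marked region listed as several intervals is broken up whatever the regional density. The shift was not run on merged peaks, so it cannot tell regional density from such cutting. The shift evens out density at 1 Mb and below, where the fullest window held 270 peaks. Regional density therefore stays open, also at that finer scale. Tandem copies of a unit of 1 kb or more, if separate in rheMac2 and with several peaks each, would make the distances between peaks repeat. The search for a repeat ran from 1 kb only up to the midpoint of each group's span. A repeat was called in 3 of 137 groups long enough to test, 2.19% (exact interval 0.454% to 6.27%). By chance 5% would be called, and 95% of 60 simulated tandem arrays were called. Those arrays all had the same unit length and number of copies, so power for other units and in groups of few peaks was not measured. The test cannot see units longer than that midpoint, evenly spaced copies with 1 peak each, or copies collapsed in rheMac2. Sequence that is present in more copies in the baboon than in rheMac2, which could raise reads over whole regions, stays open, as do clusters of marked genes; neither could be tested without read depth or a rheMac2 annotation.

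Position gives 1 hint for a part of these groups. Of the 133 on chromosomes, 12 started in the first 1 Mb of a chromosome, against a mean of 1.01 when the groups were rotated along each chromosome at random (10000 rotations, one-sided permutation p = 0.0006). Chromosome 9 alone gave 7 of the 12, with 254 peaks, and without it the count was 5 of 120 (permutation p = 0.036), on chromosomes 5, 8, 12 and 18. The group on chromosome 12 ran from 965922 to 1063191, across the 1 Mb limit, so this small count depends on where the limit is set. Groups of fewer than 10 peaks numbered 45 in the first 1 Mb against a mean of 33.4 (permutation p = 0.076). As a hypothesis, duplicated sequence near chromosome ends may account for these 12 groups; the test bears on their place, not on copy number. Another 4 groups, on chromosomes 7, 13 and 18, ended in the last 1 Mb before the last peak, which was not tested because the chromosome length was taken from that peak, and 117 groups lay in neither the first nor the last 1 Mb.

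Whether a few dense groups make the excess of a chromosome was asked for 3 chromosomes. On chromosome 9 the ratio of observed to expected fell from 1.46 by peaks to 1.06 by groups counted once (exact Poisson interval 0.927 to 1.21), so its excess is consistent with a few dense groups, and 55.6% of its peaks lay in groups of 10 or more. On chromosome 14 the ratio stayed above 1, at 1.22 (1.07 to 1.37), down from 1.52. By this interval dense groups are not the whole of its excess, but groups are not independent, so the interval is too narrow. On chromosome 19 it was 2.07 (1.80 to 2.37) by groups and 1.92 by peaks, which dense groups do not account for. Gene density, the biological explanation that stays open for chromosome 19, was not tested, since no rheMac2 annotation was used.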
